A study of Plasmodium falciparum with 16 samples.

How the data were processed

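Messenger RNA was measured in 16 libraries of Plasmodium falciparum 3D7, 4 from each of 4 groups. Per the labels, the groups were the culture at the start, and vehicle, JIB-04 E and JIB-04 Z after 6 h. Both compounds were given at 4.5 µM to trophozoites at 29 h post invasion (hpi), so the treated and vehicle groups were sampled at 35 hpi. Libraries were poly-A selected and stranded, per the labels' protocols.

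The authors deposited RPKM values (read counts divided by transcript length and library total) for 5358 transcripts, with the mean RPKM of each row beside them. STAR and edgeR are named, without versions or roles, per the submitters' processing notes. Genome build, annotation and the read counter are not given in the sources used here. Each deposited row mean was above 0.1 RPKM, the lowest being 0.101.

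Within a transcript, the deposited RPKM values of the 16 libraries were whole multiples of a step, so read counts and library totals were recovered by solving for whole numbers. All 5358 transcripts gave whole reads, within 1e-09 of a whole number, and the method returned 100% of 5356 simulated transcripts exactly. Recovered library totals ran from 10.7 to 43.7 M (mega) reads. The recovered length divisors did not belong to the transcripts beside them: 3 of 5213 equalled the transcript's own RefSeq span, and 2169 equalled the span of the gene 42 rows further on. RPKM levels of different genes are therefore not comparable here, whereas changes of a gene between libraries keep their ratio. Gene levels are printed as RPM, recovered reads scaled to a common library total as in CPM, as mean ± SD over the 4 libraries of a group.

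Of the 5358 row names, 5213 matched a locus tag of the RefSeq annotation of the 3D7 assembly, which held no symbol other than the locus tag and no product name. Gene names come from 17 lists of locus tags written from textbook knowledge before the data were examined; they were not checked against annotated products. The lists held 195 genes, of which 192 were tested and 3 (Pfs47, Pfs230 and HAP2) fell below the filter. Another 10 lists defined by product names alone were not analysed here. No coordinates are printed, because the build behind the files is not given.

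Tests used limma 3.58.1 in R 4.3.3 on log2(RPKM + 1), with a variance trend and all 16 libraries in a single fit by group, which left 12 residual degrees of freedom. Transcripts with at least 1 RPKM in at least 4 libraries were tested, 5107 in all. Adjusted p values are Benjamini-Hochberg values over these 5107, and a gene counts as changed when its adjusted p lies under 0.05. Log2 changes are on the log2(RPKM + 1) scale and are printed with their standard error (SE). This scale understates the change of genes at low RPKM, and the displaced length divisors help to set which genes those are. Sizes and ranks of change hold on this scale and can differ by RPM. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, adjusted over the 15 such lists within each comparison. camera asks whether a list stands apart from the other genes, and a list can test as lower while its own median lies above 0.

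Named genes followed a rule written before the data were examined. It takes the 10 largest rises and the 10 largest falls per comparison among changed genes whose 4 libraries of each group did not overlap and whose higher group averaged at least 10 RPKM. The text gives a subset taken from the top. The rule asked for genes with an annotated product and left out multigene families with near-identical copies. With no product names, it was applied to genes on the lists, plus at most 2 locus tags that rose and 2 that fell. Whether those locus tags belong to such families could not be checked. All members of the demethylase and sexual commitment lists are also given, with 2 to 4 members of any other list that changed most. RH2a and RH2b, falcipain-2a and falcipain-2b, and the SERA genes are related in sequence, and how shared reads were counted is not given in the sources used here, so their values are uncertain.

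The same fit was tested on simulated data with 200 changed genes among 5107. For JIB-04 Z against vehicle it recovered 88% of the genes changed by 0.5 on the log2 scale and 100% of those changed by 1, and called 17 unchanged genes. For JIB-04 E against vehicle it recovered 86% and 96% at these sizes and called 12 unchanged genes.

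The labels give every group replicates 1 to 4 without saying what a number shares. Deviations from the group means correlated between libraries of the same number at 0.38 to 0.58 for JIB-04 E and vehicle, 0.56 to 0.76 for JIB-04 Z and vehicle, 0.39 to 0.58 for the isomers, and 0.14 to 0.38 for vehicle and start. In these 4 comparisons every pair lay above 0.1, and the numbers were taken to pair the samples there. The same number gave the highest correlation in 4 of 4 cases, but in 3 of 4 for vehicle and start. There, start replicate 1 stood at 0.144 with its own number and 0.185 with another vehicle library. Vehicle replicates 1 and 2 reached 0.474 and 0.438 with a JIB-04 Z library of another number. Libraries of different numbers were thus also alike, and the pairing is an assumption. Between start and JIB-04 E, which were not compared, replicate 3 stood at 0.0489. The fit was set without a block beforehand and stayed so, with the replicate block as an alternative.

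Other alternatives, fixed before the data were examined, were pseudocounts of 0.1 and 10, no filter, and a mean RPKM of at least 10. Libraries scaled to an equal median, quantile normalization, robust variances, array weights, the 2 compared groups alone, an adjusted p under 0.01, and leaving out each library in turn were also fixed then. limma's voom on recovered reads, the same with median-of-ratios scaling, log2 RPM, quantile normalization for the list tests, and voom for named genes were added after seeing the data. Scripts used Python 3.11.15, numpy 2.4.6 and pandas 2.3.3; figures were drawn with matplotlib 3.10.9.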

Results

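Transcript levels of Plasmodium falciparum 3D7, a laboratory line of the malaria parasite, were measured in 16 poly-A selected RNA-seq libraries. Trophozoites, the feeding stage of the blood cycle, were sampled at the start, at 29 hpi, and after 6 h with vehicle, JIB-04 E or JIB-04 Z, with 4 replicate libraries in each group. JIB-04 is described in the series title as a pan inhibitor of Jumonji enzymes, which remove methyl groups from histones. E and Z are its geometric isomers about the hydrazone C=N bond, given at the same dose of 4.5 µM for the same time. Recovered depth for replicates 1 to 4 was 10.7, 43.6, 31.4 and 36.2 M (mega) reads at the start and 43.7, 29.1, 36.8 and 30.02 M in vehicle. It was 34.0, 38.1, 41.5 and 28.1 M in JIB-04 E, and 35.0, 37.7, 33.0 and 32.9 M in JIB-04 Z.

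Principal component 1 held 80.3% of the variance and separated the start from the 6 h groups, with group means of −59.3 ± 0.574 at the start, 22.5 ± 4.17 in vehicle, 16.3 ± 2.56 in JIB-04 E and 20.6 ± 3.75 in JIB-04 Z (SD, n = 4). Component 2 held 13.8% and separated JIB-04 E, at −23.5 ± 3.49, from vehicle at 12.8 ± 1.33 and JIB-04 Z at 9.29 ± 1.23.

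**Figure D1:**
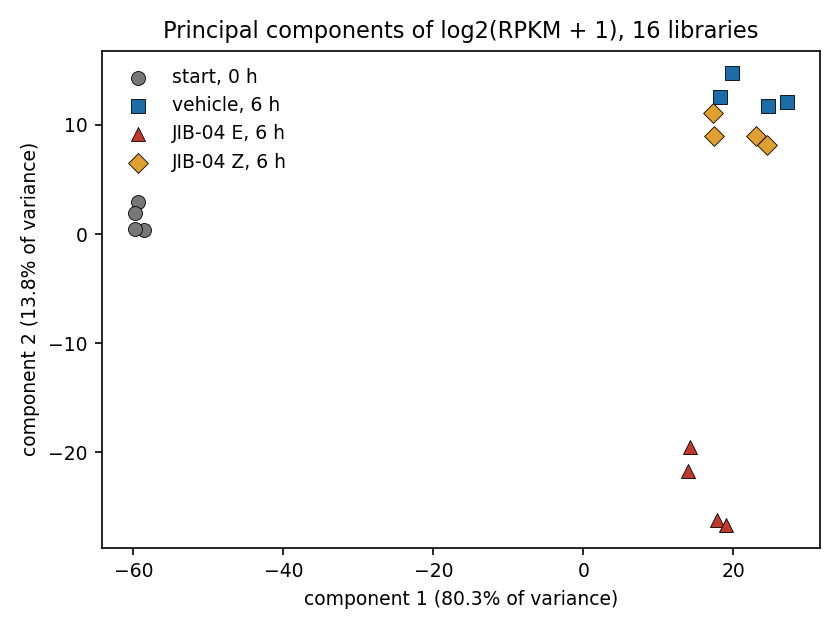
Scores of the 16 libraries on the first 2 principal components of log2(RPKM + 1), with each point a library and the share of variance on each axis. The 4 JIB-04 E libraries lie below the others on component 2, with a mean of −23.5 against 12.8 in vehicle.

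Vehicle at 6 h was compared with the start to describe the development over which the compounds acted. Of 38 genes for the surface and invasion of merozoites, the invading form built late in the cycle, 27 rose and 8 fell, and the list call was lost with an estimated correlation (adjusted p = 0.148 by limma). MSP9 (PF3D7_1228600), a merozoite surface protein, rose from 76.0 ± 1.83 to 6507 ± 875 RPM (reads scaled to a common library total, as CPM; SD, n = 4), a log2 change of 6.40 ± 0.09 (SE). SERA5 (PF3D7_0207600), a protein of parasite egress, rose from 168 ± 7.68 to 13095 ± 1136 RPM, and SIP2 (PF3D7_0604100), a DNA-binding protein of the AP2 family, from 6.39 ± 0.775 to 303 ± 46.3. SET9 (PF3D7_0508100), from the list of SET-domain methyltransferases, rose by 6.12 ± 0.07 on the log2 scale. In the other direction, DPAP1 (PF3D7_1116700), a peptidase of haemoglobin digestion, fell from 1008 ± 60.997 to 357 ± 19.1 RPM. SET5 (PF3D7_1214200), a SET-domain protein with the largest fall on the lists (−2.09 ± 0.08), went from 18.8 ± 1.85 to 3.31 ± 0.219 RPM. ENO (PF3D7_1015900), the glycolytic enolase, fell from 14822 ± 1199 to 5019.6 ± 537.

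Merozoite rises included RON3 (PF3D7_1252100) at 5.91 ± 0.08 and RhopH3 (PF3D7_0905400) at 5.27 ± 0.11. RH2b (PF3D7_1335300) and RH2a (PF3D7_1335400) were among the falls, at −1.78 ± 0.11 and −1.54 ± 0.08. Of 13 motor, egress and inner membrane complex genes, 9 rose and 3 fell (4 after either scaling). Of 20 DNA replication genes, 15 rose and 2 fell, led by FEN1 (PF3D7_0408500) at 1.43 ± 0.08. Histone transcripts rose for 7 of 8 genes, and H2A (PF3D7_0617800) went from 157 ± 4.70 to 519 ± 36.8 RPM. Histone H3.3 (PF3D7_0617900) did not pass, at 0.01 ± 0.05, and quantile normalization called 1 histone gene lower. Haemoglobin digestion had 11 falls and 2 rises among 13 genes, and glycolysis 9 falls and 2 rises among 11. Median scaling left 1 rise in each. On the log2(RPKM + 1) scale the haemoglobin falls were led by falcipain-2a (PF3D7_1115700) at −1.51 ± 0.08. By RPM falcipain-2b (PF3D7_1115300) fell more in proportion, from 19.9 to 6.19, against 380 to 130 for falcipain-2a. Ring-stage and erythrocyte remodelling genes fell in 12 of 16 cases and rose in 3, led by REX1 (PF3D7_0935900) at −1.62 ± 0.11. Late gametocyte genes fell in 6 of 8 cases and rose in 1. CCp3 (PF3D7_1407000), at −1.58 ± 0.13, had their largest fall on the log2(RPKM + 1) scale, a rank that need not hold by RPM. In the demethylase list LSD2 (PF3D7_0801900) fell by 1.30, JmjC2 (PF3D7_0602800) by 0.98, Jmj3 (PF3D7_1122200) by 0.84 and LSD1 (PF3D7_1211600) by 0.32, whereas JmjC1 (PF3D7_0809900) rose by 0.62 on the log2 scale. Of the sexual commitment genes, MDV1 (PF3D7_1216500) rose by 1.89, GDV1 (PF3D7_0935400) by 1.28, AP2-G (PF3D7_1222600) by 0.59 and Pfg27 (PF3D7_1302100) by 0.54. GEXP05 (PF3D7_0936600), Pfg14.744 (PF3D7_1477300) and Pfs16 (PF3D7_0406200) stood at −0.73, −0.62 and −0.39. GEXP02 (PF3D7_1102500) did not pass, at −0.11 ± 0.07, but was called lower after either scaling. Mixed directions were counted for SET methyltransferases (6 rose and 3 fell of 10), other chromatin regulators (5 and 4 of 10), AP2 factors (6 and 7 of 14, with AP2-L, PF3D7_0730300, at −1.93 ± 0.08) and sexual commitment (4 and 3 of 8). The same held for heat shock proteins (2 rose and 3 fell of 5, with the chaperones BiP, PF3D7_0917900, at 1.40 ± 0.07 and HSP90, PF3D7_0708400, at −1.40 ± 0.14), redox defence (2 and 5 of 8), iron and metal handling (1 and 2 of 4) and mitochondrial electron transport (1 and 1 of 2). Counts adjusted over the list alone were equal to these for all 17 lists.

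limma called 4313 of 5107 genes changed, 2014 higher and 2299 lower in vehicle, with 789 and 754 of them changed at least 2-fold. The groups did not overlap for 4070 genes, or 79.7%, where chance gives 2.86% for libraries that are not paired. By camera, histones (adjusted p = 0.00619), the merozoite list (9.22e-06), the motor list (0.0104) and DNA replication (0.00263) stood above other genes, and haemoglobin digestion (0.02003) and glycolysis (0.0289) below. With an estimated correlation none of the 15 lists passed by camera. The adjusted p values of these 6 lists then lay between 0.0891 for DNA replication and 0.374 for glycolysis. By fry all 15 passed, but fry tests a list's own genes and does not set them against other genes. With 4313 of 5107 genes changed, passing it does not set a list apart.

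JIB-04 E was compared with vehicle to find the transcripts that respond to 6 h of the compound. Genes of merozoite surface and invasion went both ways, with 19 falls and 10 rises among 38 and a list call that was lost with an estimated correlation (adjusted p = 0.0578 by limma). The largest fall on the lists was that of RAMA (PF3D7_0707300), a rhoptry membrane antigen, at 619 ± 85.5 RPM against 1904 ± 544 in vehicle (SD, n = 4), a log2 change of −1.59 ± 0.18 (SE). RhopH3, part of a complex needed for nutrient uptake, stood at 2135 ± 163 against 4871 ± 751, and the AP2 factor SIP2 at 116 ± 5.59 against 303 ± 46.3. Every one of the 8 histone genes fell, led by H2A at 304 ± 14.0 against 519 ± 36.8 RPM. Higher transcripts included RH1 (PF3D7_0402300), an invasion ligand, at 82.1 ± 4.32 against 34.6 ± 0.466, and GAMA (PF3D7_0828800), a merozoite adhesin, at 20.04 ± 1.82 against 8.43 ± 0.442. NEK4 (PF3D7_0719200), a kinase of the sexual stages, stood at 46.6 ± 8.93 against 11.01 ± 0.627 RPM, the largest rise among genes on the lists (1.72 ± 0.11).

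**Figure D2:**
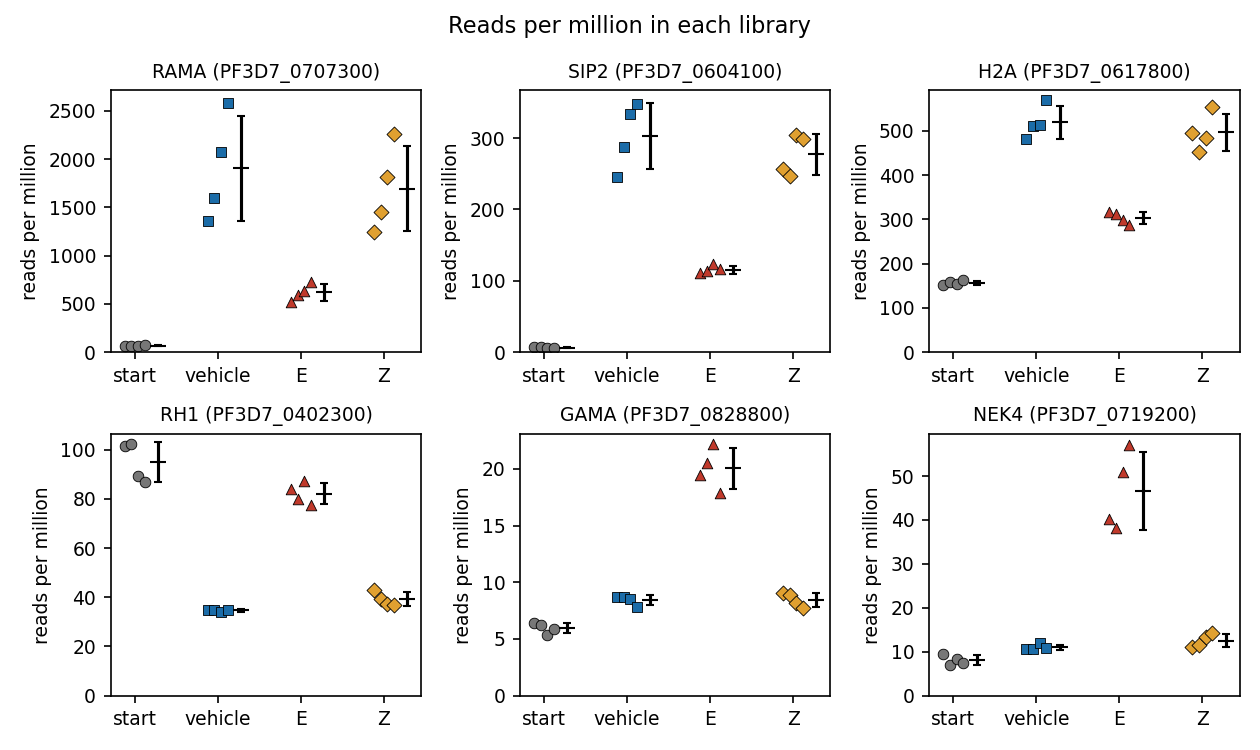
Recovered RPM of 6 genes in each of the 16 libraries, by group, with the mean and SD of each group drawn beside its 4 points. RAMA, SIP2 and histone H2A lie lower in JIB-04 E than in vehicle, and RH1, GAMA and NEK4 higher; JIB-04 Z lies near vehicle in all 6.

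Merozoite falls numbered 20 adjusted over the list alone, and either median scaling or quantile normalization gave 24 falls and 6 rises. Beyond RAMA and RhopH3, the falls were led by RAP1 (PF3D7_1410400) at −1.27 ± 0.10, RAP2 (PF3D7_0501600) at −1.19 ± 0.13, RALP1 (PF3D7_0722200) at −1.17 ± 0.18 and RON5 (PF3D7_0817700) at −1.11 ± 0.12. RAP3 (PF3D7_0501500), RON2 (PF3D7_1452000) and RhopH2 (PF3D7_0929400) followed at −1.08 ± 0.23, −1.05 ± 0.11 and −1.01 ± 0.06. RH1, GAMA and RH2b rose, the last by 1.04 ± 0.11. GAMA and RH2b, at 8.43 and 4.62 RPM in vehicle, lay in the lowest of 5 bins by vehicle level. There 75.3% of genes were called higher, with a median change of 0.55. In the motor and egress list 6 genes fell and 3 rose of 13 (8 and 0 after either scaling), with CDPK1 (PF3D7_0217500), a calcium-dependent kinase, at −0.97 ± 0.07 and the glideosome protein GAP50 (PF3D7_0918000) at −0.70 ± 0.05. Histones H4 (PF3D7_1105000) and H2B (PF3D7_1105100) changed by −0.63 ± 0.06 and −0.58 ± 0.07, and all 8 histone falls held under both scalings. Most histone genes lay in the highest of 5 bins by vehicle level, where 32.6% of genes were called lower (73.6% after median scaling). The median change of that bin was −0.04, against −0.53 for histones, a difference that was not tested. Among other chromatin regulators 3 fell and 2 rose of 10 (2 fell adjusted over the list alone; 7 fell after median scaling and 4 after quantile normalization, none rising), and heterochromatin protein HP1 (PF3D7_1220900) fell by 0.43.

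Of the 5 demethylase genes, LSD2 rose by 0.88 ± 0.13 (adjusted p = 1.64e-05 by limma) and JmjC2 by 0.77 ± 0.09 (1.22e-06), under both scalings as well. JmjC2, at 6.34 RPM in vehicle, lay in the lowest of 5 bins by vehicle level. There 75.3% of 1022 genes were called higher (50% after median scaling), with a median change of 0.55. The rise of JmjC2 is thus not separate from that of weakly expressed genes. Jmj3 passed as deposited, at 0.27 ± 0.10 (adjusted p = 0.0314 by limma), but stood at −0.01 after median scaling. JmjC1, at −0.12 ± 0.08 (adjusted p = 0.190 by limma), and LSD1, at 0.11 ± 0.08 (0.278), did not pass in this fit, which leaves out the pairs. JmjC1 was called lower after either scaling. In replicates 1 to 4 LSD1 stood at 365, 333, 337 and 288 RPM in JIB-04 E, against 331, 305, 309 and 280 in vehicle. LSD1 was thus higher in each pair as deposited, and a small rise is not ruled out. Sexual commitment genes rose in 7 of 8 cases, where 2796 of all 5107 tested genes were called higher. By camera neither this list (adjusted p = 0.264) nor the demethylase list (0.798) stood apart from other genes. Pfg27 (PF3D7_1302100) rose by 0.69 ± 0.11, MDV1 (PF3D7_1216500) by 0.66 ± 0.14, GEXP05 (PF3D7_0936600) by 0.59 ± 0.07 and Pfg14.744 (PF3D7_1477300) by 0.42 ± 0.09. AP2-G (PF3D7_1222600), the regulator of sexual commitment, rose by 0.40 ± 0.08, GEXP02 (PF3D7_1102500) by 0.34 ± 0.07 and Pfs16 (PF3D7_0406200) by 0.19 ± 0.05, whereas GDV1 (PF3D7_0935400) stood at 0.03 ± 0.10 (adjusted p = 0.796 by limma). After median scaling the 3 genes Pfg27, MDV1 and GEXP05 still passed, Pfs16 stood at −0.10, and quantile normalization gave 4 rises and 1 fall, that of GDV1. All 8 late gametocyte genes tested lay in the lowest of 5 bins by vehicle level, where 75.3% of 1022 genes were called higher (50% after median scaling), so their rise is not separate from that of weakly expressed genes. Late gametocyte genes rose in 6 of 8 cases (5 after either scaling, with 1 fall after quantile normalization), among them CCp2 (PF3D7_1455800) by 1.20 ± 0.06 and Pfs48/45 (PF3D7_1346700) by 1.05 ± 0.09.

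The AP2 factors had 7 rises and 4 falls among 14 genes (4 and 7 after median scaling, 4 and 4 after quantile normalization), with AP2-O (PF3D7_1143100) at 0.94 ± 0.07 and AP2-L (PF3D7_0730300) at 0.77 ± 0.08. Ring-stage and remodelling genes rose in 12 of 16 cases with no fall (4 rises and 2 falls after median scaling, 4 and 1 after quantile normalization), led by the export chaperone HSP101 (PF3D7_1116800) at 0.76 ± 0.10 and PTP2 (PF3D7_0731100) at 0.67 ± 0.08. Haemoglobin digestion had 9 rises and no fall among 13 genes (2 and 2 after median scaling, 5 and 1 after quantile normalization), led by plasmepsin-I (PF3D7_1407900) at 0.53 ± 0.08. By camera the ring-stage (adjusted p = 0.264) and haemoglobin (0.581) lists did not stand apart from other genes. DNA replication had 4 rises and 6 falls among 20 (0 and 16 after median scaling, 4 and 8 after quantile normalization), with the origin protein ORC5 (PF3D7_0215800) at 0.39 ± 0.05 and the helicase subunit MCM5 (PF3D7_1211700) at −0.33 ± 0.05. SET methyltransferases had 4 rises and 4 falls among 10 (3 and 5, or 1 and 4), glycolysis 4 and 1 among 11 (0 and 5, or 2 and 1; 2 rises adjusted over the list alone), and heat shock proteins 3 and 2 among 5 (0 and 2, or 3 and 2). Redox defence had 3 rises and 1 fall among 8 (0 and 3, or 3 and 2), iron and metal handling 3 and 0 among 4 (0 and 2, or 0 and 1), and mitochondrial electron transport 1 and 1 among 2 (0 and 1 under both). Among their changed members were SET5 at 0.55 ± 0.08 (0.00 after quantile normalization), SET2 (PF3D7_1322100) at 0.51 ± 0.08, GAPDH (PF3D7_1462800) and ENO of glycolysis at 0.32 ± 0.12 and 0.32 ± 0.09, and the chaperone HSP70-1 (PF3D7_0818900) at 0.56 ± 0.11. Also changed were gGCS (PF3D7_0918900), of glutathione synthesis, at 0.46 ± 0.07, thioredoxin Trx1 (PF3D7_1457200) at −0.43 ± 0.06, the ferrochelatase FC (PF3D7_1364900) at 0.50 ± 0.10 and DHODH (PF3D7_0603300), of pyrimidine synthesis, at 0.41 ± 0.06. Unless given, counts adjusted over the list alone were equal. Of transcripts without a name, PF3D7_1040300 rose by 2.47 ± 0.13 and PF3D7_1033800 by 2.21 ± 0.16, and PF3D7_0704500 fell by 1.65.

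limma called 3323 of 5107 genes changed between JIB-04 E and vehicle, 2796 higher and 527 lower, with 314 higher and 24 lower by at least 2-fold (142 and 56 after median scaling). The median gene stood at 0.24, and scaling the libraries to an equal median moved it to −0.04 and the calls to 1277 higher and 1665 lower; quantile normalization gave 1306 and 1471. With and without median scaling, 1277 genes were called higher both times and 527 lower both times. Median scaling lowers the genes of JIB-04 E libraries nearly alike, so this overlap follows from the direction of the shift and is no separate support. The groups did not overlap for 2895 genes, or 56.7%, where chance gives 2.86% for libraries that are not paired. By camera, histones (adjusted p = 4.02e-09) and the motor list (0.000201) stood below other genes, and both passed with an estimated correlation (adjusted p = 0.0133 each). camera does not match genes by level, so these calls do not allow for the lower changes of strongly expressed genes. The merozoite list (3.96e-08), DNA replication (0.00932) and other chromatin regulators (0.0295) passed camera but not with an estimated correlation, where the adjusted p was 0.0578, 0.0578 and 0.152. The motor list had a median of 0.00 and a mean of −0.17, and DNA replication a median of 0.01 and a mean of −0.00, although both tested as lower than other genes.

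**Figure D3:**
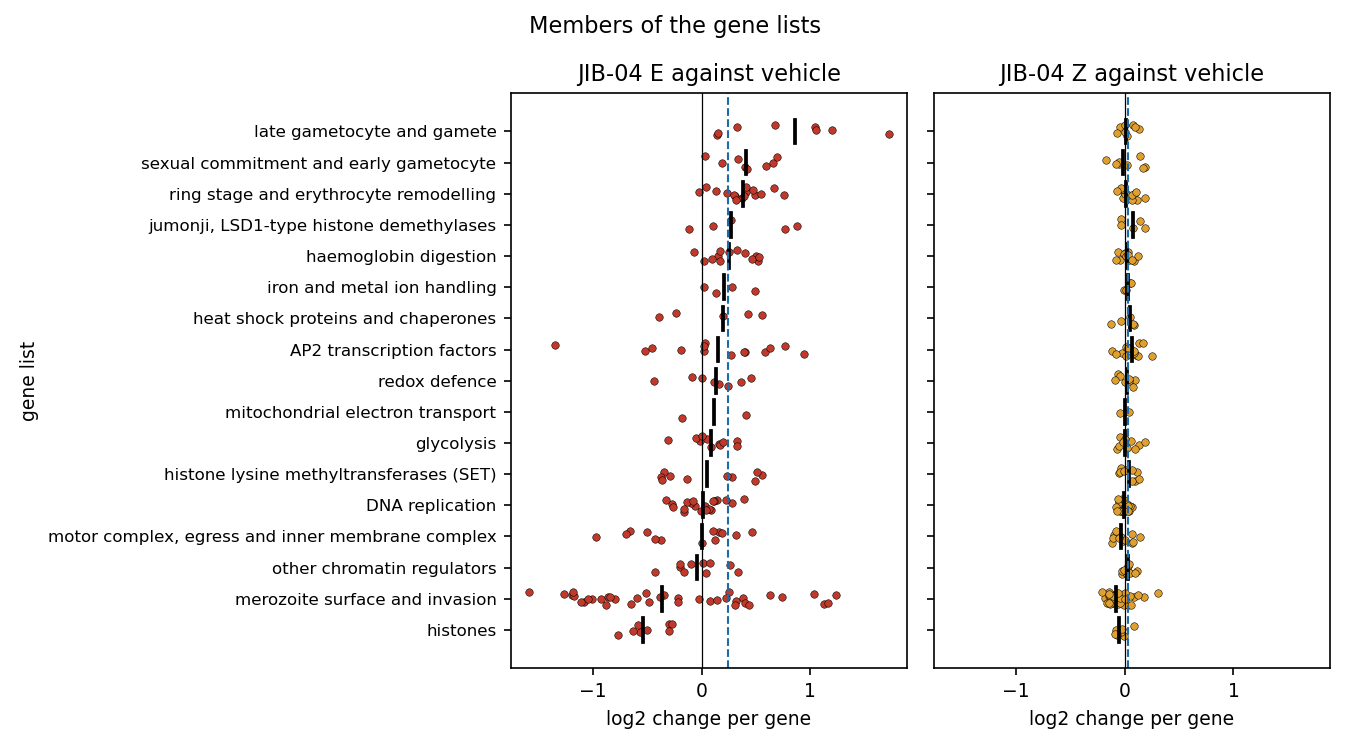
Log2 change of each tested member of the 17 gene lists in JIB-04 E against vehicle (left) and JIB-04 Z against vehicle (right), with each point a gene, each black bar a list's median, and the dashed line the median of all tested genes. The histone median is −0.53 in JIB-04 E and −0.05 in JIB-04 Z, as deposited and without further scaling.

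JIB-04 Z was compared with vehicle at the same dose and time. RAMA stood at 1694 ± 443 RPM against 1904 ± 544 in vehicle (SD, n = 4), with a log2 change of −0.16 and a 95% interval from −0.55 to 0.23. The intervals were −0.33 to 0.09 for SIP2, −0.20 to 0.07 for histone H2A, −0.09 to 0.36 for NEK4 and −0.16 to 0.16 for GAMA. RH1 stood at 39.2 ± 2.78 against 34.6 ± 0.466 RPM, with an interval from 0.04 to 0.31 and an adjusted p of 0.817 by limma. In the demethylase list the log2 changes were 0.19 ± 0.13 for LSD2, 0.15 ± 0.09 for JmjC2, 0.07 ± 0.08 for LSD1, −0.03 ± 0.08 for JmjC1 and −0.03 ± 0.10 for Jmj3. Sexual commitment genes lay between GEXP05 at 0.19 ± 0.07 (adjusted p = 0.919 by limma) and GDV1 at −0.17 ± 0.10 (0.997).

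limma called 0 of 5107 genes, and the smallest adjusted p was 0.774; 240 genes had an unadjusted p under 0.05, where 223 did by voom, which also called 0. With the replicate block, which compares within pairs, limma also called 0 genes, with a smallest adjusted p of 0.0990, but 647 genes had an unadjusted p under 0.05, where chance gives 255. In that fit the 95% interval was −0.38 to 0.05 for RAMA, 0.07 to 0.28 for RH1 and 0.04 to 0.34 for LSD2, and lay within ±0.5 for 97.8% of genes. The change had the same sign in all 4 pairs for 1435 genes, or 28.1%, where chance gives 12.5% for independent genes; this count was chosen after seeing the data. Small changes under JIB-04 Z are therefore not ruled out. None of the members of the 17 lists passed, over all genes or adjusted over the list alone. The 95% interval of the change lay within ±0.5 for 96.1% of genes and within ±1 for 99.5%, and the groups did not overlap for 143 genes, or 2.80%. Chance gives 2.86% for libraries that are not paired, so with these pairs the 2 shares do not show an absence of change. By camera, the merozoite list (adjusted p = 6.92e-06, median −0.08), histones (0.0121, −0.05), the motor list (0.0224, −0.04) and DNA replication (0.0340, −0.01) stood slightly below other genes. None held with an estimated correlation, where the adjusted p was 0.261 for histones and 0.158 for each of the other 3, and fry called 0 lists.

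The isomers were compared directly to test their difference. NEK4 stood 1.59 ± 0.11 higher on the log2 scale in JIB-04 E than in JIB-04 Z, at 46.6 ± 8.93 against 12.5 ± 1.56 RPM (SD, n = 4), and GAMA and RH1 stood 1.16 ± 0.07 and 1.06 ± 0.06 higher. RAMA was lower in JIB-04 E, at 619 ± 85.5 against 1694 ± 443 RPM (−1.43 ± 0.18), as were SIP2 at −1.22 ± 0.10, RAP1 at −1.13 ± 0.10 and CDPK1 at −0.94 ± 0.07. All 8 histone genes were lower in JIB-04 E, with H2A at −0.70 ± 0.06, and remained so under both scalings. LSD2 and JmjC2 were higher in JIB-04 E by 0.69 ± 0.13 and 0.62 ± 0.09 (JmjC2 did not pass after quantile normalization), and Jmj3 by 0.30 ± 0.10, which neither scaling kept. The difference did not pass for JmjC1, with a 95% interval from −0.24 to 0.08 (called lower after either scaling), for LSD1, from −0.14 to 0.21, or for GDV1, from −0.02 to 0.43. These intervals leave out the pairs. In replicates 1 to 4 GDV1 stood at 5.21, 6.38, 5.03 and 6.25 RPM in JIB-04 E, against 4.95, 5.22, 4.81 and 4.38 in JIB-04 Z. Within each pair GDV1 and LSD1 were higher and JmjC1 lower in JIB-04 E, so small differences are not ruled out.

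Merozoite genes were higher in JIB-04 E in 10 cases and lower in 18 of 38 (8 and 23 after median scaling, 6 and 20 after quantile normalization), and motor and egress genes in 2 and 6 of 13 (0 and 7, or 1 and 8). Late gametocyte genes were higher in 6 of 8 (5 under both scalings) and sexual commitment genes in 7 of 8 (2, or 3), led by MDV1 at 0.71 ± 0.14; none was lower. AP2-G stood at 0.48 ± 0.08, Pfg27 at 0.53 ± 0.11, GEXP05 at 0.41 ± 0.07, GEXP02 at 0.32 ± 0.07, Pfg14.744 at 0.29 ± 0.09 and Pfs16 at 0.24 ± 0.05, the last turning to −0.02 after median scaling. AP2 factors had 5 higher and 4 lower of 14 (4 and 7, or 2 and 5), SET methyltransferases 4 and 4 of 10 (1 and 5, or 0 and 5), and other chromatin regulators 2 and 4 of 10 (0 and 7, or 0 and 6; 5 lower adjusted over the list alone). Ring-stage genes were higher in 11 of 16, with 12 adjusted over the list alone (3 higher and 1 lower, or 3 and 0), and haemoglobin digestion genes in 9 of 13 (1 and 2, or 4 and 1). Over all tested genes, 2612 of 5107 were called higher. By camera the sexual commitment (adjusted p = 0.183), ring-stage (0.183) and haemoglobin (0.452) lists did not stand apart from other genes. DNA replication had 4 higher and 4 lower of 20 (1 and 16, or 4 and 7; 3 lower adjusted over the list alone). Counts in brackets are after median scaling and then quantile normalization. In the remaining lists 1 and 1 of 11 glycolysis genes (0 and 5, or 0 and 1), 3 and 2 of 5 heat shock genes (0 and 2, or 3 and 2), 3 and 1 of 8 redox genes (0 and 2, or 3 and 1), 3 and 0 of 4 iron genes (0 and 1 under both) and 1 and 1 of 2 electron transport genes (0 and 1 under both) were higher and lower.

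limma called 3102 of 5107 genes different between the isomers, 2612 higher and 490 lower in JIB-04 E, with 238 and 17 by at least 2-fold (104 and 44 after median scaling). The median gene stood at 0.21, and after median scaling the calls were 1133 higher and 1559 lower, with 1202 and 1336 after quantile normalization. By camera, histones (adjusted p = 3.73e-09), the motor list (0.000231), the merozoite list (6.92e-07), DNA replication (0.0145) and other chromatin regulators (0.0136) stood below other genes, and late gametocyte genes, all weakly expressed, above (0.0225). With an estimated correlation, histones and the motor list passed (adjusted p = 0.0133 each), and the other 4 did not, at 0.0661 for the merozoite, DNA replication and late gametocyte lists and 0.0975 for other chromatin regulators. As in the comparison with vehicle, these tests did not match genes by level. The motor list had a median of 0.02 and a mean of −0.16, and DNA replication a median of 0.02 and a mean of 0.00, while testing as lower. SET methyltransferases had an adjusted p of 0.0698 by limma's camera and 0.0438 with the replicate block, but 0.0975 with an estimated correlation, 0.243 after median scaling and 0.167 after quantile normalization.

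**Figure D4:**
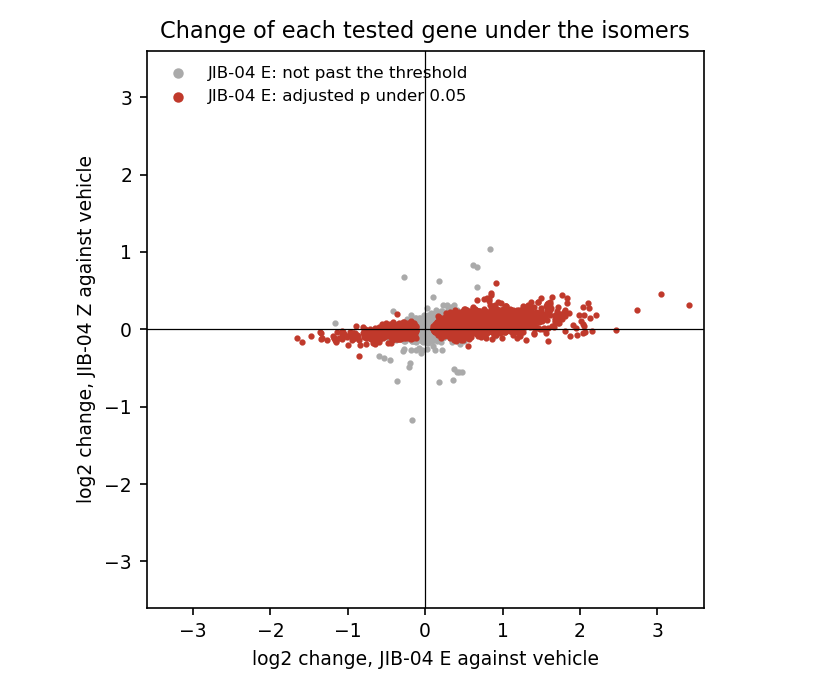
Log2 change against vehicle of each tested gene in JIB-04 E (horizontal) and JIB-04 Z (vertical), with red points for genes called in JIB-04 E by limma. The red points spread along the horizontal axis, and 0 genes were called in JIB-04 Z.

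Over all 5107 tested genes, the change under each compound was regressed on the change from start to vehicle, with vehicle libraries split so that none entered both axes. If development were the only difference, a slope of 0 would be as much development as vehicle and −1 none. The JIB-04 E change also differed by vehicle level, with a median of 0.55 in the lowest of 5 bins and −0.04 in the highest. The slope does not separate this from slower development. JIB-04 E had a slope of −0.144 ± 0.0239 over replicates (SD, n = 4; −0.167 to −0.117), and JIB-04 Z −0.0276 ± 0.0420 (−0.0647 to 0.0155). Within replicate pairs the slopes differed by −0.116 ± 0.0186 (SD, n = 4), below 0 in 4 of 4 pairs, with a two-sided exact sign-flip p of 0.125, the smallest that 4 pairs give. An exact permutation over 70 arrangements gave 0.0286, but it ignores the pairs; both tests were chosen after seeing the data. Across genes, which are not independent replicates, development accounted for 13.8% of the variance of the JIB-04 E changes (r = −0.37). Directions were also counted with the vehicle libraries split 2 and 2, a setting chosen after seeing the data, so that no library entered both comparisons (mean of 6 splits). Of genes changed in both, 1512 were lower in vehicle than at the start and then higher in JIB-04 E, 375 higher and then lower, 576.5 higher in both and 49.3 lower in both, where independent directions would give 1298, 161, 791 and 264. After median scaling these counts were 663, 919, 255.5 and 300.3, against 414, 669.95, 504.5 and 549.4.

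The changes of the isomers against the shared vehicle libraries correlated across genes at r = 0.52. In 100 simulations with both groups unchanged, r had a mean of 0.50 and a highest value of 0.57. JIB-04 E was not unchanged: its changes had a variance of 0.191, against 0.00843 for JIB-04 Z. The simulated r is therefore no reference for the observed r and decides nothing about it. The covariance of the isomers' changes was 0.0209 against 0.00525 simulated, a difference of 0.0157. With the vehicle libraries split 2 and 2, r was 0.25 and the covariance 0.0135. No gene was called in both, and 0 were expected, since JIB-04 Z had no calls. Projected on the JIB-04 E change of the other 3 replicates, the JIB-04 Z change came to 9.39% ± 1.22 of its size (SD, n = 4; 8.19% to 11.02%), above 0 in 4 of 4 replicates. The left-out JIB-04 E replicate came to 95.9% ± 11.7; this projection was chosen after seeing the data, and its exact sign-flip p of 0.125, two-sided, is the smallest that 4 replicates give.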

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

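In 10 of 230 groups of 4 libraries, or 4.35%, the highest or lowest library lay further from the others than a 95% limit for a single outlying value allows; chance does so in about 1 in 20 groups. Mitochondrial rows took 99.1 RPM in JIB-04 Z replicate 3, below 165 to 169 in the other 3. Replicate 3 was also the lowest in vehicle, at 87.9 against 161 to 189, and in JIB-04 E, at 399 against 444 to 523. At the start it stood at 154 against 160 to 179, so the low value is not particular to JIB-04 Z. RH2b (PF3D7_1335300), an invasion ligand, stood at 10.6 RPM in JIB-04 E replicate 1, above 9.36 to 9.56. The AP2 factor AP2-O (PF3D7_1143100) stood at 28.5 in vehicle replicate 1, above 25.9 to 26.2. RhopH2 (PF3D7_0929400), a rhoptry protein, stood at 116 in start replicate 1, above 106 to 107, and at 2260.1 in vehicle replicate 1, below 2521 to 2542. PF3D7_0704500 stood at 12.1 in start replicate 1, above 9.26 to 9.59. PF3D7_1121400 stood at 2.37 in JIB-04 Z replicate 1, below 2.68 to 2.73. RH2a (PF3D7_1335400) stood at 6.69 in vehicle replicate 4, below 7.50 to 7.64. PF3D7_1478700 stood at 37.9 in JIB-04 E replicate 4, above 33.1 to 33.9. The demethylase gene JmjC1 (PF3D7_0809900) stood at 62.3 in JIB-04 E replicate 4, below 70.5 to 71.8. Start replicate 1, with 10.7 M (mega) reads, was the shallowest library.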

How the results depend on the processing

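Results under voom, median-of-ratios scaling, RPM and, for the list tests, quantile normalization come from alternatives chosen after seeing the data. Over 14 alternatives the counts of changed genes ranged as follows: 2530.0 to 3858 for JIB-04 E against vehicle, 0 for JIB-04 Z, 2357 to 3731 between the isomers and 3461 to 4531 for vehicle against start. Leaving out 1 library gave 3112 to 3283, 0, 2852 to 3014 and 4225 to 4263. With the replicate block, which uses the pairing of the libraries, the counts were 3858, 0, 3731 and 4531; for JIB-04 Z the genes with an unadjusted p under 0.05 went from 240 to 647. The block made 1 new list call (SET methyltransferases between the isomers, not called with an estimated correlation, median scaling or quantile normalization) and changed no other list call.

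The share of calls that were higher in JIB-04 E than in vehicle was 84.1% as deposited, 43.4% after median scaling, 47.0% after quantile normalization and 48.5% by voom with median-of-ratios scaling. Direction relative to all other RNA therefore rests on how libraries are scaled, and these libraries hold no external standard among the rows used here.

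List tests moved most. With an estimated correlation, 2 lists passed for JIB-04 E against vehicle, 0 for JIB-04 Z, 2 between the isomers and 0 for vehicle against start, where camera gave 5, 4, 6 and 6. In the same order, 10, 0, 8 and 15 passed by fry, 3, 1, 5 and 5 after quantile normalization, and 6, 4, 6 and 6 after median scaling, where late gametocyte genes gained a call for JIB-04 E against vehicle (adjusted p = 0.0106 by limma, 0.0546 unscaled). fry asks another question than camera; otherwise the cause was not tested. Of lists passed by camera, 73 results by setting kept their direction and call, 30 lost the call and 2 reversed: DNA replication under fry, with a median of 0.015 for JIB-04 E against vehicle (adjusted p = 0.983 by limma's fry) and 0.016 between the isomers (0.470).

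Of named genes, 1316 results by setting kept direction and call, 25 lost the call and 3 reversed, all after median scaling: Jmj3 at −0.012 and Pfs16 at −0.096 for JIB-04 E against vehicle, and Pfs16 at −0.018 between the isomers. Those shifts follow from the scaling, which lowers the genes of a JIB-04 E library nearly alike. AP2-G, Pfg14.744 and GEXP02 lost their calls against vehicle under both scalings; between the isomers GEXP05, Pfg14.744 and GEXP02 did under both, Pfg27 after median scaling, and AP2-G and JmjC2 after quantile normalization. Jmj3 against vehicle also lost its call without JIB-04 E replicate 3 (0.26) or 4 (0.20), and without vehicle replicate 1 (0.21) or 2 (0.24). Between the isomers it lost its call without JIB-04 E replicate 4 (0.23) and without JIB-04 Z replicate 1 (0.24) or 2 (0.25).

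The slope of JIB-04 E on development ranged from −0.157 to −0.131 over the alternatives and from −0.156 to −0.130 leaving out 1 library, and that of JIB-04 Z from −0.0281 to −0.0263 and from −0.0420 to −0.0105. The correlation of the isomers' changes ranged from 0.52 to 0.57, and from 0.44 to 0.55 leaving out 1 library; it stood at 0.44, 0.45 and 0.47 without JIB-04 Z replicates 1, 3 and 4. Of simulated changes of 0.5, 82% to 90% were recovered, depending on the comparison. The simulation used the residual spread of each gene. Depth, which ran from 10.7 to 43.7 M reads, did not enter it, so its effect was not tested there.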

Other observations

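The tests of splits, of scaling by a single factor, of variation between libraries, of DNA carry-over on the apicoplast rows and of displaced lengths were chosen only after the results they bear on were seen. Rows named for the mitochondrion, 26 of 31 of which were tested, rose together in JIB-04 E: 20 rose and 1 fell against vehicle, and the same counts held against JIB-04 Z. They took 452 ± 51.4 RPM in JIB-04 E, 152 ± 44.5 in vehicle, 151 ± 34.4 in JIB-04 Z and 167 ± 11.8 at the start (SD, n = 4). Rows named mal_rna, whose identity is not given in the sources used here, rose in 9 of 10 tested cases with no fall, from 147 ± 58.1 RPM in vehicle to 349 ± 53.6 in JIB-04 E. JIB-04 Z against vehicle had 0 calls by limma in either set.

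For the mitochondrial rows, a single factor per library as the cause is argued against, since 20 rows were still called higher and 4 lower after median scaling. Variation from library to library that does not follow the groups is argued against too. The lowest JIB-04 E library held 2.11 times the highest of the other 12, 399 against 189 RPM. A cause other than the compound that all JIB-04 E libraries share cannot be told apart from treatment. DNA carry-over stays open and cannot be told apart, because the 2 apicoplast rows differ by comparator and hold few reads. They took 24 reads in JIB-04 E, 25 in vehicle, 22 at the start and 7 in JIB-04 Z. Scaled to RPM these were 0.178, 0.178, 0.198 and 0.0517, so JIB-04 Z was the low group. Allowing for library totals, JIB-04 E stood at 0.945 of vehicle (95% interval 0.517 to 1.72) and 3.35 of JIB-04 Z (1.40 to 9.21), with intervals that cover counting error only. No biological explanation was tested.

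Weakly expressed genes rose more than others in JIB-04 E. By 5 equal bins of the level at the start, from lowest to highest, the median log2 change against vehicle was 0.48, 0.31, 0.23, 0.22 and 0.05, and in JIB-04 Z 0.04, 0.04, 0.03, 0.02 and 0.02. The lowest bin exceeded the highest by 0.429 ± 0.0377 (SD over 4 replicate pairs), which a single factor per library cannot give, and by 0.567 ± 0.0279 among 849 genes within 0.2 between vehicle and start, which less development in 6 h does not predict. An even background of reads over the genome cannot be told apart: the 10th percentile of the gain per kb in the lowest bin was −0.391 of the median gain, and all 4 replicate pairs lay below the bound of 0.25 set for it (highest −0.0725), but their SD of 0.662 exceeds the distance to that bound. No biological explanation was tested.

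The RPKM divisors fit a length column displaced against the gene names, since 2169 equalled the span of the gene 42 rows further on and 3 their own, and 42 rows are not named PF3D7. Displaced gene names are argued against: the merozoite list had a median log2 change from start to vehicle of 3.22 as deposited, −0.279 with the values 42 rows before each name and −0.258 with those 42 rows after. Changes of a gene between libraries are not touched by its divisor apart from the filter and pseudocount; RPM in place of RPKM gave 3398 changed genes for JIB-04 E against vehicle. No biological explanation was tested.

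Among the 35 splits of the 8 libraries into 4 and 4, 1 split, the real one, gave as many genes in 3 comparisons. By this count alone, chance can be excluded there only if the libraries are taken as unpaired. With the pairs kept, the 8 splits that part all 4 pairs are too few for a share under 0.05. The fit with the replicate block, which compares within pairs, argues against chance there. It called 3858 genes for JIB-04 E against vehicle, 3731 between the isomers and 4531 for vehicle against start. The real counts were 3323 for JIB-04 E against vehicle, 3102 between the isomers and 4313 for vehicle against start, with 0 in the highest other split each time, the 7 others that part all pairs included. For JIB-04 Z against vehicle the real count was 0, so all 35 splits gave as many by construction and decide nothing about chance. There, 1 other split, replicates 1 and 2 of both groups against replicates 3 and 4, called 1308 genes. It keeps the pairs whole and so points to a structure of the samples; the 7 other splits that part all pairs called 0, as did the fit with the replicate block.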
